A study of Rattus norvegicus with 43 samples.

How the data were processed

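Messenger RNA of A7r5 cells, a smooth muscle cell line from rat aorta, was measured with Affymetrix rat expression arrays, which carry short probes grouped into probe sets and read mainly the 3' ends of transcripts. There were 43 arrays in 9 groups, set by the folic acid of the medium (2.5, 10 or 100 ng/ml, which the labels call deficient, sufficient and excess) and by 7, 14 or 21 days of culture, with 4 or 5 arrays per group. Groups and replicate numbers were taken from the sample titles. The titles also carry a running serial number, which goes up to 56. The serials follow the order of the groups up to 45, and the 11 arrays above 45 do not, so these were treated as a possible array series. Within it, serials 53 to 56 are all excess arrays of days 14 and 21. A covariate for the whole series cannot separate that block from excess medium, while serials up to 45 alone leave it out. The titles give the serial 22 to 3 arrays and the serial 50 to 2, for a reason the labels do not state.

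The deposited table holds log2 expression values of 31099 probe sets, which the authors obtained with GCRMA, per the submitters' processing notes. GCRMA corrects each array for background by probe sequence, normalizes the arrays by quantiles and summarizes the probes of each set. The notes also name limma, and they give no version of either tool. The values lay between 0.84 and 15, and the median of an array between 3.66 and 3.72, so the arrays had already been brought to one scale. No scanner files were used here, so the background correction could not be changed. A low value in such a table is close to background, and a fold change against it understates or blurs the true ratio. Correlations between replicate arrays of a group lay between 0.9912 and 0.998, and 0 pairs of arrays held identical values. The number of arrays limits the precision of each value.

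Probe sets were named with the platform annotation, and symbols were updated through the Entrez identifier in a table of RefSeq genes of the GRCr8 assembly, used only for names. Of the probe sets, 20832 had 1 gene symbol, 436 had several and were not named, and 9831 had no entry. The identifier matched for 20764 of the named probe sets and did not for 68, and 0 symbols changed. Control probe sets, 57 in all, were left out of the tests. A probe set was kept if its log2 value was above 4 in at least 4 arrays, and each gene was represented by its probe set with the highest mean over all arrays, which left 9095 genes of 14218. For 2393 genes several probe sets passed the filter, and disagreement in sign among them is stated where such a gene is named.

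All arrays entered one linear model of the 9 group means in limma 3.58.1 under R 4.3.3, with 34 residual degrees of freedom and moderated variances (4.12 prior degrees of freedom). Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and the threshold was an adjusted p of 0.05. Planned comparisons numbered 11. They were deficient against sufficient, excess against sufficient and deficient against excess medium at each day, the difference of the deficiency effect between day 21 and day 7, and sufficient medium at day 21 against day 7. Another 2, the differences of the excess effect between day 21 and the earlier days, were added after the excess comparisons had been seen. Errors of log2 fold changes are standard errors of the model, and errors of group levels are SDs. Plots were drawn with Python 3.11.15, matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.

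Before the values were seen, 34 gene lists with 908 symbols had been fixed. They cover folate transport and the folate cycle, the methionine cycle and transsulfuration, purine and pyrimidine synthesis, DNA and histone methylation, DNA damage response and repair, DNA replication, mitosis, p53 targets, senescence, imprinted genes, the integrated stress response, endoplasmic reticulum chaperones, oxidative stress, oxidative phosphorylation, hypoxia and glycolysis, cholesterol synthesis, lipid storage and oxidation, lysosome and autophagy, ribosomal proteins, immediate early genes, inflammatory genes, interferon response, smooth muscle contractile genes, skeletal and cardiac muscle markers, extracellular matrix, matrix remodelling enzymes, adhesion receptors, the Wnt, TGF-beta and BMP pathway, calcification, and markers of fibroblasts, adipocytes, endothelial cells, epithelial cells and macrophages. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, again with a correlation estimated for each list, and with fry. Camera compares a list with all other genes.

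The rule for named genes had also been fixed. It took the 5 highest and 5 lowest fold changes past the threshold, with values that did not overlap between the groups, for deficient medium and for time, and the 3 highest and 3 lowest for the other comparisons. It added up to 3 members of each list past the threshold in deficient medium, on the day with the most, and genes of folate metabolism. Where fewer than 3 genes passed, the 3 with the smallest p were named. Placeholder symbols were counted and not named. A further rule, written after the values were seen, named up to 3 past-threshold members of each list called in excess medium. Together these gave 117 genes, or 63 without that further rule, the genes of the 2 added comparisons included. Of the folate genes, Mtr did not pass the filter.

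Alternatives fixed beforehand were quantile normalization, no filter, a stricter filter (log2 above 6), each probe set on its own, leaving out probe sets that may match several transcripts, the replicate number as a block, the array series as a covariate, trended and robust variances, array weights, only the groups compared, and each array left out in turn. Those chosen after seeing the data were the 3' minus 5' difference of the beta-actin control probe sets as a covariate, leaving out the 8 arrays above 2.2 in that difference, each array series alone, and leaving out serials 46 to 49. Replicate numbers were checked for pairing by the correlation of deviations from the group means.

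The model was tested on simulated data, with 200 of 9095 genes changed and 10 draws per size of change. For deficient against sufficient medium at day 21 it recovered 16.7% of changes of 0.25 on the log2 scale, 78.6% of changes of 0.5 and 98.9% of changes of 1. At day 7 the same shares were 13.5%, 73.5% and 98.3%. For the difference of the deficiency effect between days they were 1.4%, 44.6% and 94%. The simulated noise was independent between genes, whereas in the data 27.7% of the variance around the group means lay on 1 component. With 200 genes changed at once the adjustment is also milder than where few genes change. The shares therefore do not give the power in the data, least of all where few genes change.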

Results

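The 43 arrays measured expression in A7r5 rat aortic smooth muscle cells kept in deficient, sufficient or excess folic acid. Day 7 had 4 deficient, 5 sufficient and 4 excess arrays, and days 14 and 21 had 5 of each. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. The first principal component, with 52.9% of the variance, ordered the groups by day, and the second, with 17%, separated excess medium at days 14 and 21 from the rest. The study asks how folate deficiency acts on these cells, and the excess medium gives a further dose.

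Time in culture was the largest source of change in sufficient medium, and it is the background to the folate comparisons. From day 7 to day 21, Mgp, which encodes an inhibitor of calcification, rose from 5.21 ± 0.24 to 11.45 ± 0.13 (log2, SD, n = 5 and 5), or 75.5-fold. Scg2, a secretory granule protein, rose by 5.00 ± 0.10, Art3 by 4.75 ± 0.14 from a level near background, S1pr1, a receptor for sphingosine phosphate, by 4.62 ± 0.12, and Tcim by 4.54 ± 0.17. Mybl2, a transcription factor of dividing cells, fell by 3.97 ± 0.17, and Cdca3 and Sgo1, both of mitosis, by 3.11 ± 0.13 and 2.97 ± 0.11. Atoh8 fell by 3.15 ± 0.11 to near background. Id2, an inhibitor of helix-loop-helix transcription factors, fell by 2.92 ± 0.15.

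With time in sufficient medium, all 28 measured mitosis genes and all 26 replication genes fell, with median log2 changes of -2.22 and -1.61, and 13 of 16 skeletal and cardiac muscle markers rose, with a median of 1.56 (28, 26 and 13 adjusted over the list alone). Camera called 16 of 31 lists, and 10 with an estimated correlation, these 3 among them at adjusted p = 0.00017, 0.00024 and 0.00021. DNA repair genes fell (22 of 24, median -0.68), as did purine and pyrimidine synthesis (20 of 22 lower, -0.64), the integrated stress response (20 of 27 lower, -0.73), chaperones (15 of 20 lower, -0.45) and cholesterol synthesis (15 of 19 lower, -0.77). Lysosome genes rose (16 of 23, 0.45), as did inflammatory genes (8 of 13, 0.45). In all, 5696 of 9095 genes passed in limma, 2688 higher and 3008 lower.

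Deficient medium at day 7 gave 0 genes past the threshold against sufficient medium in limma, the smallest adjusted p being 0.159, with 551 genes at an unadjusted p below 0.05 where 455 would arise by chance. The 3 genes with the smallest p, none past the threshold, were Dsn1, a kinetochore protein, at 9.01 ± 0.11 against 8.49 ± 0.28 (SD, n = 4 and 5; adjusted p = 0.16 in limma), Cyp1a1, a xenobiotic-metabolizing enzyme near background, with a difference of 0.55 ± 0.12, and Mgst3, a microsomal glutathione transferase, with 0.45 ± 0.10. Among the genes of folate metabolism, Mthfd2 differed by 0.08 ± 0.15, Tyms by 0.07 ± 0.15, Shmt2 by 0.03 ± 0.14, Slc19a1 by 0.02 ± 0.11 and Folr1, near background, by -0.07 ± 0.12. With array weights 10 genes passed, and 1 passed without deficient replicate 1 or without sufficient replicate 1.

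At day 7, camera called 4 lists as higher in deficient medium and 0 with an estimated correlation. The calcification list had a median of 0.25 over 6 members, none past the threshold and 3 higher adjusted over the list alone (adjusted p = 0.000686, and adjusted p = 0.28 with an estimated correlation). Replication had a median of 0.07 (adjusted p = 0.0338, and adjusted p = 0.64 with an estimated correlation), oxidative phosphorylation 0.05 (0.0338, and adjusted p = 0.7 with an estimated correlation) and smooth muscle contractile genes 0.10 (0.0261, and adjusted p = 0.64 with an estimated correlation), with 0 members of each adjusted over the list alone. In serials up to 45 the last 3 lost their calls (adjusted p = 0.087, 0.087 and 0.12), while calcification had a median of 0.21 there and 0.20 with the array series as a covariate. Without a filter its median was 0.06 and its call was lost.

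By day 14 in deficient medium 8 genes had changed, 3 higher and 5 lower (n = 5 and 5). Txnip, which encodes an inhibitor of thioredoxin and of glucose uptake, fell from 5.23 ± 0.24 to 4.08 ± 0.21 (SD), 2.21-fold, at adjusted p = 1.4e-05 in limma, and as the lower level lies just above the filter limit of 4 this fold is inexact. Trib3, a pseudokinase induced in the integrated stress response, rose by 0.72 ± 0.13 (adjusted p = 0.012), Psph, the last enzyme of serine synthesis, by 0.44 ± 0.09 (0.046) and Hecw2, a ubiquitin ligase, by 0.76 ± 0.14 (0.013). Cdc20, an activator of the anaphase-promoting complex, fell by 0.62 ± 0.13, Rrad, a small GTPase, by 0.53 ± 0.12 and Pdpn, a membrane glycoprotein, by 0.42 ± 0.09. Tbl1xr1, a subunit of a transcriptional corepressor complex, fell by 0.55 ± 0.10, while 3 of its 4 probe sets had the opposite sign. Mthfd2 differed by 0.22 ± 0.14, Tyms by 0.26 ± 0.14, Shmt2 by 0.14 ± 0.13, and Slc19a1 and Folr1 by -0.05 ± 0.11 each, none past the threshold. In sufficient replicate 4 Mthfd2 was at 8.64, where the others lay at 7.72 to 7.93. That array has serial 49, among the serials 46 to 49 that stand apart, and its title alone ends in R. Without that array Mthfd2 differed by 0.38, also not past the threshold.

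Of 27 integrated stress response genes at day 14, 2 rose in deficient medium and 3 were higher adjusted over the list alone (median 0.08, adjusted p = 2.08e-05, and adjusted p = 0.012 with an estimated correlation). Oxidative stress genes had a median of 0.05, with 0 of 19 past the threshold and 5 higher adjusted over the list alone (0.000972, and adjusted p = 0.044 with an estimated correlation). Of 9 fibroblast markers, Pdpn fell and 4 were lower adjusted over the list alone (median -0.08, 0.000972, and adjusted p = 0.012 with an estimated correlation). The mitosis list had a median of -0.18, with 1 of 28 lower and 9 lower adjusted over the list alone (3.24e-08, but adjusted p = 0.051 with an estimated correlation). Extracellular matrix genes (median -0.14, 4 lower adjusted over the list alone, adjusted p = 0.32 with an estimated correlation), replication (0.07, 0.32 likewise), hypoxia and glycolysis (0.05, 0.28 likewise) and immediate early genes (0.05, 0.19 likewise) were called only at the preset correlation.

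The 8 genes depended on the settings: Txnip kept its call in each, while the largest adjusted p of the others lay between 0.062 for Trib3 and 0.28 for Psph. With the array series as a covariate 21 genes passed, these 8 among them, and in serials up to 45 it was 9, with 4 of the 8 among them. The series above 45, with 1 array of each group, was not fitted. The stress response median was 0.08 with the covariate and 0.06 in serials up to 45, and the mitosis median -0.18 and -0.21. Leaving out deficient replicate 1 or sufficient replicate 3 left 1 gene, leaving out sufficient replicate 5 gave 27 and leaving out deficient replicate 5 gave 14. When arrays were exchanged between the groups, 5 of 100 splits, the real one included, called at least as many genes, and 1 of them called 1250.

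At day 21, 71 genes differed between deficient and sufficient medium, 37 higher and 34 lower (n = 5 and 5), 13 of them by at least 1.5-fold. Txnip fell from 7.45 ± 0.18 to 5.87 ± 0.14 (SD), 2.98-fold, at adjusted p = 2.8e-09 in limma. Trib3 rose from 7.82 ± 0.18 to 8.78 ± 0.12, and Ddit3, which encodes the stress-induced transcription factor CHOP, from 9.29 ± 0.11 to 9.96 ± 0.10, at adjusted p = 5.9e-05 and 0.00024. Mthfd2, a mitochondrial enzyme of the folate cycle, rose by 0.57 ± 0.14 (0.031). Tfrc, the transferrin receptor, rose by 0.62 ± 0.09 and Gadd45a, a growth arrest gene, by 0.67 ± 0.14. Myh3 and Myh2, myosin heavy chains of embryonic and fast skeletal muscle, rose by 0.76 ± 0.12 and 0.83 ± 0.17, and Id1, a target of BMP signalling, by 0.58 ± 0.10. Arhgap20l1 fell by 1.01 ± 0.15, Emilin1, an elastic fibre glycoprotein, by 0.67 ± 0.13, Eepd1 by 0.58 ± 0.13 and Fam13b by 0.54 ± 0.09, with 1 of its 2 probe sets of opposite sign.

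The integrated stress response list was higher in deficient medium at day 21, where 6 of 27 members rose and 1 fell, or 13 and 1 adjusted over the list alone (median 0.18, adjusted p = 7.35e-11, and adjusted p = 0.00022 with an estimated correlation). Mitosis genes were lower, with 2 of 28 past the threshold and 12 adjusted over the list alone (median -0.21, 2.18e-11, and adjusted p = 0.026 with an estimated correlation). Aurka, a mitotic kinase, fell by 0.50 ± 0.12 and Racgap1, needed for cytokinesis, by 0.43 ± 0.08. The median shifts of these lists were 0.15 and -0.22 with the array series as a covariate and 0.18 and -0.28 among serials up to 45, where both kept their calls. Of the folate list, Mthfd2 rose and the other 16 of 17 did not pass (median 0.09, 1 higher adjusted over the list alone, adjusted p = 0.00357, but adjusted p = 0.071 with an estimated correlation). Slc19a1, the reduced folate carrier, differed by 0.30 ± 0.11 (adjusted p = 0.21), Shmt2 by 0.26 ± 0.13 (0.41), Folr1 by 0.03 ± 0.11 (0.95) and Tyms, thymidylate synthase, by -0.05 ± 0.14 (0.92).

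Hypoxia and glycolysis genes had 0 of 24 members past the threshold and 5 higher adjusted over the list alone (median 0.08, adjusted p = 5.29e-05, but adjusted p = 0.063 with an estimated correlation). Of 16 skeletal and cardiac muscle markers 2 rose and Tnnt2, the cardiac troponin T, fell by 0.23 ± 0.06, or 5 and 2 adjusted over the list alone (median 0.09, 0.0026, but adjusted p = 0.063 with an estimated correlation). With the array series as a covariate the skeletal muscle list lost its call (adjusted p = 0.052). The extracellular matrix list had a median of -0.14, with Emilin1 lower and 3 lower adjusted over the list alone (0.00159, but adjusted p = 0.44 with an estimated correlation). Members of lists not called were Ezh2, a histone methyltransferase, which fell by 0.37 ± 0.08, Sdf2l1, of the endoplasmic reticulum, by 0.45 ± 0.10, Nrp1, a co-receptor of VEGF, by 0.31 ± 0.08, and Msh6, of mismatch repair, which rose by 0.21 ± 0.05.

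All 71 genes were among 323 that passed with the array series as a covariate, and 56 were among 122 that passed in serials up to 45. Deficient medium had no array above 45 at day 21, so that series gives no value of its own. Leaving out deficient replicate 3 left 32 genes, deficient replicate 5 left 34 and sufficient replicate 4 left 33, against 41 without deficient replicate 6, sufficient replicate 1 or sufficient replicate 3, and 44 without deficient replicate 4. Nrp1, Msh6, Tnnt2, Mthfd2, Ezh2, Aurka, Sdf2l1, Eepd1, Gadd45a and Myh2 lost their calls in at least 1 setting, with a largest adjusted p between 0.056 for Gadd45a and 0.19 for Nrp1. With array weights Slc19a1 passed.

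The deficiency effect itself differed between day 21 and day 7 for 4 genes, 2 in each direction, tested as an interaction in limma. Myh3 differed by 1.22 ± 0.17 (adjusted p = 8e-05) and Maoa, an enzyme of amine breakdown, by 0.36 ± 0.07 (0.024), while Txnip differed by -1.50 ± 0.21 (8e-05) and Arhgap20l1 by -1.09 ± 0.22 (0.028). The values of Myh3 and Arhgap20l1 are inexact, because at day 7 Myh3 was at 3.78 in deficient and 4.25 in sufficient medium and Arhgap20l1 at 4.33 and 4.26, under or just above the filter limit of 4. Camera called 7 lists on this difference, and 0 with an estimated correlation. The integrated stress response list had a median of 0.12, with 0 of 27 past the threshold and 6 higher adjusted over the list alone (adjusted p = 0.063 with an estimated correlation). The mitosis list had a median of -0.25, with 0 of 28 past the threshold and 6 lower adjusted over the list alone (adjusted p = 0.068 with an estimated correlation). With the array series as a covariate 54 genes passed, these 4 among them, and 8 in serials up to 45. Leaving out single arrays gave between 2 genes, without deficient day 7 replicate 5, and 7, without deficient day 7 replicate 1. Arhgap20l1 lost its call in 13 of 33 settings and Maoa in 7 of 32, with a largest adjusted p of 0.11 and 0.09 in limma. Myh3 and Txnip kept theirs in each.

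**Figure D1:**
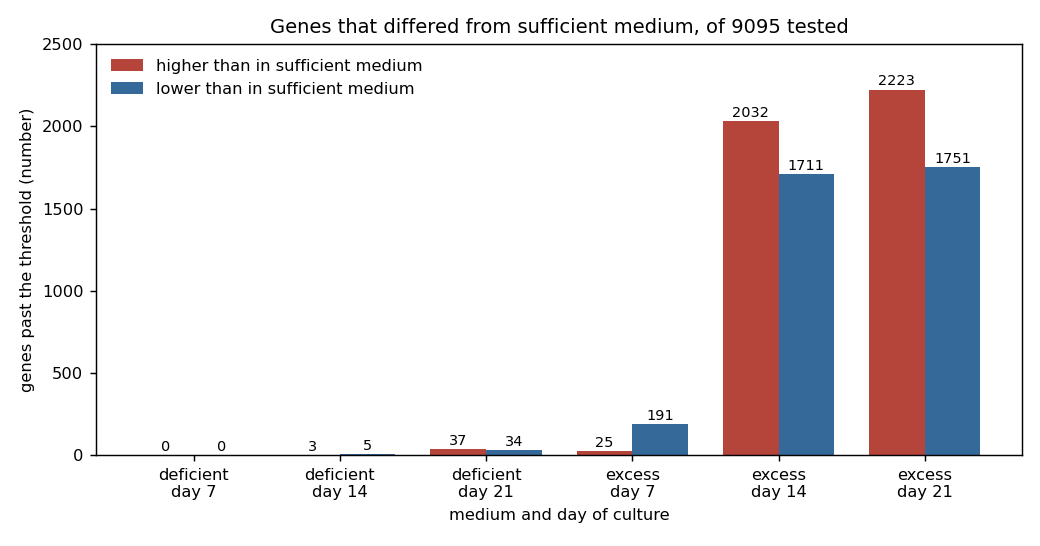
Number of genes past the threshold (vertical axis) in deficient and in excess medium against sufficient medium at each day (horizontal axis), of 9095 tested, with separate bars for genes higher and genes lower. Deficient medium goes from 0 to 8 to 71 genes in all, and excess medium from 216 to 3743 to 3974.

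Excess medium at day 7 changed 216 genes, 25 higher and 191 lower than in sufficient medium (n = 4 and 5), 20 of them by at least 1.5-fold. Cox6a2, the muscle form of a cytochrome oxidase subunit, fell from 8.05 ± 0.15 to 7.22 ± 0.30 (SD), 1.78-fold, at adjusted p = 1.3e-05 in limma. Casp4, an inflammatory caspase, fell by 0.70 ± 0.11 and Bnip3, a mitophagy receptor induced by low oxygen, by 0.69 ± 0.10. Pttg1 (securin) rose by 0.64 ± 0.14, Cdc20 by 0.63 ± 0.14 and Fscn1, an actin-bundling protein, by 0.56 ± 0.11. The value of Fscn1 is inexact, as its level of 4.1 in sufficient medium lies just above the filter limit of 4. Mthfd2 fell by 0.52 ± 0.15 (adjusted p = 0.048), while Tyms differed by -0.32 ± 0.15, Shmt2 by -0.25 ± 0.14, Slc19a1 by -0.06 ± 0.11 and Folr1, near background, by 0.13 ± 0.12, none past the threshold.

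At day 7 the mitosis list was higher in excess medium, where 4 of 28 members rose, Cenpe and Aurka among them by 0.50 ± 0.13 and 0.50 ± 0.12, and 10 rose adjusted over the list alone (median 0.20, adjusted p = 6.13e-16, and adjusted p = 0.0062 with an estimated correlation). Chaperones were higher (median 0.09, 0 of 20 past the threshold and 0 adjusted over the list alone, 3.12e-05, and adjusted p = 0.0062 with an estimated correlation). Hypoxia and glycolysis genes were lower, with 5 of 24 down and 1 up, or 14 and 1 adjusted over the list alone (median -0.21, 1.69e-06, and adjusted p = 0.018 with an estimated correlation). Slc2a1, the glucose transporter, fell by 0.67 ± 0.11 and Pfkp, of glycolysis, by 0.61 ± 0.12. Integrated stress response genes were lower, with 4 of 27 down and 10 adjusted over the list alone (median -0.19, 0.000135, and adjusted p = 0.018 with an estimated correlation). Trib3 fell by 0.58 ± 0.14 and Slc3a2, part of an amino acid transporter, by 0.30 ± 0.07. Skeletal muscle markers (median -0.27, with Tnnc2 lower by -0.26 ± 0.06 and 8 lower adjusted over the list alone, adjusted p = 0.26 with an estimated correlation), adhesion receptors (median 0.03, 0 adjusted over the list alone, adjusted p = 0.6 with an estimated correlation) and DNA and histone methylation (median 0.02, 0 likewise, adjusted p = 0.26 with an estimated correlation) were called only at the preset correlation.

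The median change of all genes at day 7 was -0.06, and after quantile normalization 140 genes passed, 31 higher and 109 lower. Counts were 379 with the array series as a covariate, 672 in serials up to 45, 25 without the arrays above the beta-actin limit (21 of them among the 216, and all 216 kept their sign there, with a slope of 0.88 on the fold changes of all arrays) and 0 with only these arrays in the fit, and the series above 45, with 1 array of each group, was not fitted. The mitosis median was 0.20 with the covariate and 0.14 in serials up to 45, the hypoxia median -0.21 and -0.24, the stress response median -0.20 and -0.22 and the chaperone median 0.09 and 0.10. In serials up to 45 skeletal muscle markers and DNA and histone methylation lost their calls (adjusted p = 0.10 and 0.064), and without a filter skeletal muscle markers had a median of -0.01 and lost theirs. Leaving out single arrays gave from 64 genes without excess replicate 3, through 70 without excess replicate 1, 76 and 82 without sufficient replicates 2 and 1, 99 without excess replicate 4 and 338 without sufficient replicate 6, to 544 without excess replicate 6. Each of the day 7 genes named here as past the threshold lost its call when only the arrays of these groups entered the fit.

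By day 14 excess medium had changed 3743 of 9095 genes, 2032 higher and 1711 lower (n = 5 and 5), 759 of them by at least 1.5-fold. Txnip rose from 5.23 ± 0.24 to 8.20 ± 0.29 (SD), 7.84-fold, at adjusted p = 1.6e-18 in limma, the opposite of its direction in deficient medium. Kif20a, a mitotic kinesin, rose by 2.28 ± 0.17 and Cdc20 by 2.17 ± 0.13. Prnd, which encodes the prion-like protein doppel, fell by 2.35 ± 0.10. Tnnt1, the slow skeletal troponin T, fell by 2.10 ± 0.15 and Lbp, a lipopolysaccharide-binding protein, by 2.05 ± 0.24. Of the folate genes, Mthfd2 fell by 0.64 ± 0.14 (adjusted p = 0.00029), Shmt2 by 0.57 ± 0.13 and Slc19a1 by 0.47 ± 0.11, while Tyms differed by 0.05 ± 0.14 and Folr1 by -0.18 ± 0.11.

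All 28 mitosis genes rose at day 14, as they did adjusted over the list alone, with a median of 1.39 (adjusted p = 7.46e-41, and adjusted p = 6e-06 with an estimated correlation). Bub1b, of the spindle checkpoint, rose by 2.07 ± 0.11. Of 26 replication genes 23 rose, the same number adjusted over the list alone (median 0.64, 1.34e-13, and adjusted p = 0.0018 with an estimated correlation). Among them Orc1 rose by 1.61 ± 0.23, Cdt1 by 1.19 ± 0.12 and Pola1 by 1.13 ± 0.11. Of 19 cholesterol synthesis genes 13 rose, or 14 adjusted over the list alone (median 0.45, 5.87e-07, and adjusted p = 0.0031 with an estimated correlation). Idi1, of isoprenoid synthesis, rose by 1.45 ± 0.09, Insig1, which restrains sterol synthesis, by 0.89 ± 0.08 and Stard4 by 0.85 ± 0.11, which lost its call when probe sets that may match several transcripts were left out. In these arrays the beta-actin 3' minus 5' difference, a sign of RNA integrity or labelling, was 2.21 ± 0.64 in excess against 1.65 ± 0.16 in sufficient medium (SD, n = 5 and 5).

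Integrated stress response genes fell at day 14, with 18 of 27 lower and 1 higher, or 19 and 1 adjusted over the list alone (median -0.40, adjusted p = 4.98e-10, and adjusted p = 0.00023 with an estimated correlation). Ddit3 fell by 1.79 ± 0.11, Trib3 by 1.73 ± 0.13 and Atf5 by 1.09 ± 0.14. Of 24 hypoxia and glycolysis genes 17 fell and 1 rose, the same adjusted over the list alone (median -0.38, 1.25e-06, and adjusted p = 0.014 with an estimated correlation). Pfkl, with an SD of 0.99 in sufficient medium, fell by 1.38 ± 0.40 and lost its call without the arrays above the beta-actin limit, while Pfkp fell by 1.00 ± 0.11 and Vegfa by 0.84 ± 0.09. Of 16 skeletal muscle markers 9 fell and 2 rose, or 10 and 2 adjusted over the list alone (median -0.60, 1.92e-05, and adjusted p = 0.0048 with an estimated correlation). Without a filter, when members near background enter the list, this median was -0.06 and the call was kept. Acta1, skeletal actin, fell by 1.57 ± 0.11 and Myh3 by 1.17 ± 0.12. Oxidative stress genes (9 of 19 lower and 1 higher, the same adjusted over the list alone, median -0.17, adjusted p = 0.014 with an estimated correlation) included Srxn1, Gsta4 and Nqo1, which fell by 0.83 ± 0.10, 0.79 ± 0.12 and 0.72 ± 0.08. The p53 targets (9 of 17 lower and 1 higher, the same adjusted over the list alone, median -0.17, adjusted p = 0.042 with an estimated correlation) included Gadd45a, which fell by 1.68 ± 0.14, Sesn2 by 0.91 ± 0.14 and Phlda3 by 0.60 ± 0.10.

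A further 6 lists were called at day 14 only at the preset correlation. These were ribosomal proteins (14 of 21 lower, 14 adjusted over the list alone, median -0.14, adjusted p = 0.34 with an estimated correlation) and smooth muscle contractile genes (13 of 22 lower, 13 lower and 2 higher adjusted over the list alone, median -0.21, adjusted p = 0.18 with an estimated correlation), with the 4 lists that follow. Rpl28, near background, Rpl11 and Rpl14 fell by 0.28 ± 0.10, 0.20 ± 0.07 and 0.18 ± 0.06. Des (desmin), Csrp1 and Pdlim7 fell by 0.92 ± 0.14, 0.68 ± 0.11 and 0.60 ± 0.16, with 1 of 2 probe sets of Pdlim7 of opposite sign. Lysosome genes (11 of 23 lower and 1 higher, 12 and 1 adjusted over the list alone, median -0.18, adjusted p = 0.078 with an estimated correlation) included Psap, Ctsd and Gabarapl1, which fell by 0.76 ± 0.19, 0.58 ± 0.12 and 0.53 ± 0.06. Psap had an SD of 0.49 in excess medium at day 14 and was at -0.35 in serials up to 45, and Ctsd lost its call without the arrays above the beta-actin limit. DNA and histone methylation genes (11 of 22 higher and 1 lower, the same adjusted over the list alone, median 0.17, adjusted p = 0.12 with an estimated correlation) included Ezh2, Uhrf1 and Tet2, which rose by 1.09 ± 0.08, 0.93 ± 0.13 and 0.74 ± 0.13. DNA repair genes (10 of 24 higher and 2 lower, the same adjusted over the list alone, median 0.10, adjusted p = 0.078 with an estimated correlation) included Blm, Exo1 and Ung, up by 1.28 ± 0.15, 0.98 ± 0.16 and 0.89 ± 0.11. In the Wnt, TGF-beta and BMP list (9 of 21 lower and 3 higher, the same adjusted over the list alone, median -0.16, adjusted p = 0.078 with an estimated correlation), Tgfb1, Id1 and Bambi fell by 1.41 ± 0.52, 0.78 ± 0.10 and 0.75 ± 0.09. Tgfb1 had an SD of 1.46 in sufficient medium and lost its call with the array series as a covariate, without the arrays above the beta-actin limit, with only these groups in the fit, and without any 1 of sufficient replicates 1, 2 and 3 or excess replicates 3 and 5.

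Without the 8 arrays above the beta-actin limit, which leaves 2 excess arrays, 2133 genes passed, 902 higher and 1231 lower, with 1884 of them among the 3743, and 3713 of the 3743 kept their sign. With the beta-actin difference as a covariate 1624 were higher and 1792 lower, so which direction prevails at day 14 depends on how RNA integrity is handled. Without these arrays the p53 targets, ribosomal proteins and the Wnt, TGF-beta and BMP list lost their calls (adjusted p = 0.073, 0.10 and 0.26). With the array series as a covariate 3427 passed, and in serials up to 45 alone, with 2 excess and 4 sufficient arrays, 2294. The series above 45 has 1 sufficient array at day 14 and so gives no replicated value. The mitosis median was 1.35 with the covariate and 1.37 in serials up to 45, the replication median 0.72 and 0.68 and the cholesterol median 0.45 and 0.45. The stress response median was -0.41 and -0.40, the hypoxia median -0.36 and -0.33, the skeletal muscle median -0.59 and -0.58, and the smooth muscle median -0.17 and -0.21. The Wnt, TGF-beta and BMP list lost its call in both (adjusted p = 0.052 and 0.091), and DNA repair in serials up to 45 (0.087). Rpl11 and Rpl14 lost their calls without the arrays above the limit, and their largest adjusted p over all settings was 0.82 and 0.80.

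At day 21 in excess medium 3974 genes differed from sufficient medium, 2223 higher and 1751 lower (n = 5 and 5), 1008 of them by at least 1.5-fold. Prnd fell from 11.40 ± 0.16 to 7.15 ± 0.18 (SD), 19.1-fold, at adjusted p = 3.1e-30 in limma. Tnnt1 fell by 3.14 ± 0.15. F3, the tissue factor that starts coagulation, fell by 2.96 ± 0.10. Insig1 rose from 5.87 ± 0.07 to 8.79 ± 0.19, 7.53-fold, Col25a1, a membrane collagen, by 2.72 ± 0.16 and Lum, the matrix proteoglycan lumican, by 2.88 ± 0.20 from a level near background. Of the folate genes, Tyms rose by 0.57 ± 0.14 (adjusted p = 0.0013) and Shmt2 by 0.46 ± 0.13, Mthfd2 fell by 0.47 ± 0.14 and Folr1 by 0.44 ± 0.11, and Slc19a1 differed by -0.18 ± 0.11 (adjusted p = 0.19).

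Of 28 mitosis genes 27 rose at day 21, the same number adjusted over the list alone (median 1.12, adjusted p = 5.22e-27, and adjusted p = 0.00012 with an estimated correlation). Cdc20, Kif11 and Kif20a rose by 2.05 ± 0.13, 1.80 ± 0.14 and 1.67 ± 0.17. Of 26 replication genes 25 rose, the same adjusted over the list alone (median 0.85, 3.85e-15, and adjusted p = 0.00074 with an estimated correlation). The helicase subunits Mcm7 and Mcm5 rose by 1.58 ± 0.08 and 1.06 ± 0.15. Of 19 cholesterol synthesis genes 17 rose, the same adjusted over the list alone (median 0.94, 3.85e-15, and adjusted p = 2.9e-05 with an estimated correlation). Idi1 rose by 2.64 ± 0.09 and Sqle, squalene epoxidase, by 1.55 ± 0.12. DNA repair genes rose, with 12 of 24 higher, also adjusted over the list alone (median 0.25, 0.000842, and adjusted p = 0.013 with an estimated correlation). Blm rose by 1.30 ± 0.15, Chek1 by 0.99 ± 0.09 and H2ax by 0.97 ± 0.13. The beta-actin 3' minus 5' difference was 2.22 ± 0.41 in excess and 1.71 ± 0.16 in sufficient medium (SD, n = 5 and 5).

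Skeletal and cardiac muscle markers were lower at day 21, with 11 of 16 down and 2 up, the same adjusted over the list alone (median -0.95, adjusted p = 1.89e-08, and adjusted p = 0.00036 with an estimated correlation). Without a filter the median of the skeletal muscle list was -0.02, with the call kept. Acta1 fell by 2.79 ± 0.11 and Myh2 by 2.70 ± 0.17, to near background. Of 22 smooth muscle contractile genes 14 fell, the same adjusted over the list alone (median -0.31, 2.96e-07, and adjusted p = 0.039 with an estimated correlation). Mylk, the myosin light chain kinase, fell by 1.09 ± 0.07, Myh11, the smooth muscle myosin, by 0.89 ± 0.11 and Cnn1, calponin, by 0.82 ± 0.05. Of 24 hypoxia and glycolysis genes 18 fell and 1 rose, or 19 and 1 adjusted over the list alone (median -0.34, 1.23e-07, and adjusted p = 0.0081 with an estimated correlation). Pfkp, Vegfa and P4ha2 fell by 1.58 ± 0.11, 1.11 ± 0.09 and 1.00 ± 0.07. Oxidative stress genes (7 of 19 lower and 2 higher, the same adjusted over the list alone, median -0.19, adjusted p = 0.037 with an estimated correlation) included Gsta4, Gpx1 and Srxn1, down by 1.12 ± 0.12, 1.04 ± 0.06 and 0.99 ± 0.10. In the Wnt, TGF-beta and BMP list (7 of 21 lower and 6 higher, 8 and 6 adjusted over the list alone, median -0.23, adjusted p = 0.045 with an estimated correlation) Id1, Id2 and Id3 fell by 2.71 ± 0.10, 2.34 ± 0.15 and 1.21 ± 0.14. The median of the Wnt, TGF-beta and BMP list was -0.05 without a filter, and that of oxidative stress genes -0.06 without the arrays above the beta-actin limit, with both calls kept.

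The integrated stress response list had 14 of 27 members lower and 4 higher at day 21, the same adjusted over the list alone (median -0.24, adjusted p = 0.00505, but adjusted p = 0.066 with an estimated correlation). Ddit3, Trib3 and Asns fell by 1.54 ± 0.11, 1.46 ± 0.13 and 0.67 ± 0.07. Lysosome genes (8 of 23 lower, the same adjusted over the list alone, median -0.16, adjusted p = 0.11 with an estimated correlation) included Psap, Ctsz and Lamp2, down by 0.82 ± 0.19, 0.54 ± 0.11 and 0.46 ± 0.05, with 1 of 2 probe sets of Lamp2 of opposite sign. Psap had an SD of 0.68 in excess medium at day 21 and went from -1.46 in serials above 45 to -0.35 without the arrays above the beta-actin limit, with its call kept. DNA and histone methylation genes (7 of 22 higher, 6 adjusted over the list alone, median 0.18, adjusted p = 0.11 with an estimated correlation) included Uhrf1, Ezh2 and the methyltransferase Dnmt1, up by 1.23 ± 0.13, 1.04 ± 0.08 and 0.87 ± 0.14. The calcification list (5 of 6 lower and 1 higher, the same adjusted over the list alone, median -0.52, adjusted p = 0.17 with an estimated correlation) included the phosphate transporters Slc20a2 and Slc20a1, both down by 0.63, and Enpp1, which makes pyrophosphate, down by 0.56 ± 0.08. Without a filter the calcification median was -0.01 and the call was lost.

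Without the arrays above the beta-actin limit, which leaves 2 excess arrays at day 21, 2619 genes passed, 2450 of them among the 3974, and Tyms, Shmt2, Mthfd2 and the calcification list lost their calls. With the array series as a covariate 4220 passed, in serials up to 45 alone 2989 and in serials above 45 alone, with 2 arrays of each group, 1934. The mitosis median was 1.12, 1.12 and 1.18 in these, the replication median 0.85, 0.85 and 0.83, the cholesterol median 0.94, 1.07 and 0.84 and the DNA repair median 0.25, 0.30 and 0.27. The skeletal muscle median was -0.95, -0.95 and -1.07, the smooth muscle median -0.31, -0.33 and -0.31, and the hypoxia median -0.34, -0.33 and -0.34. Methylation genes lost their call in serials up to 45 (adjusted p = 0.084) and the Wnt, TGF-beta and BMP list in serials above 45 (0.095).

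**Figure D2:**
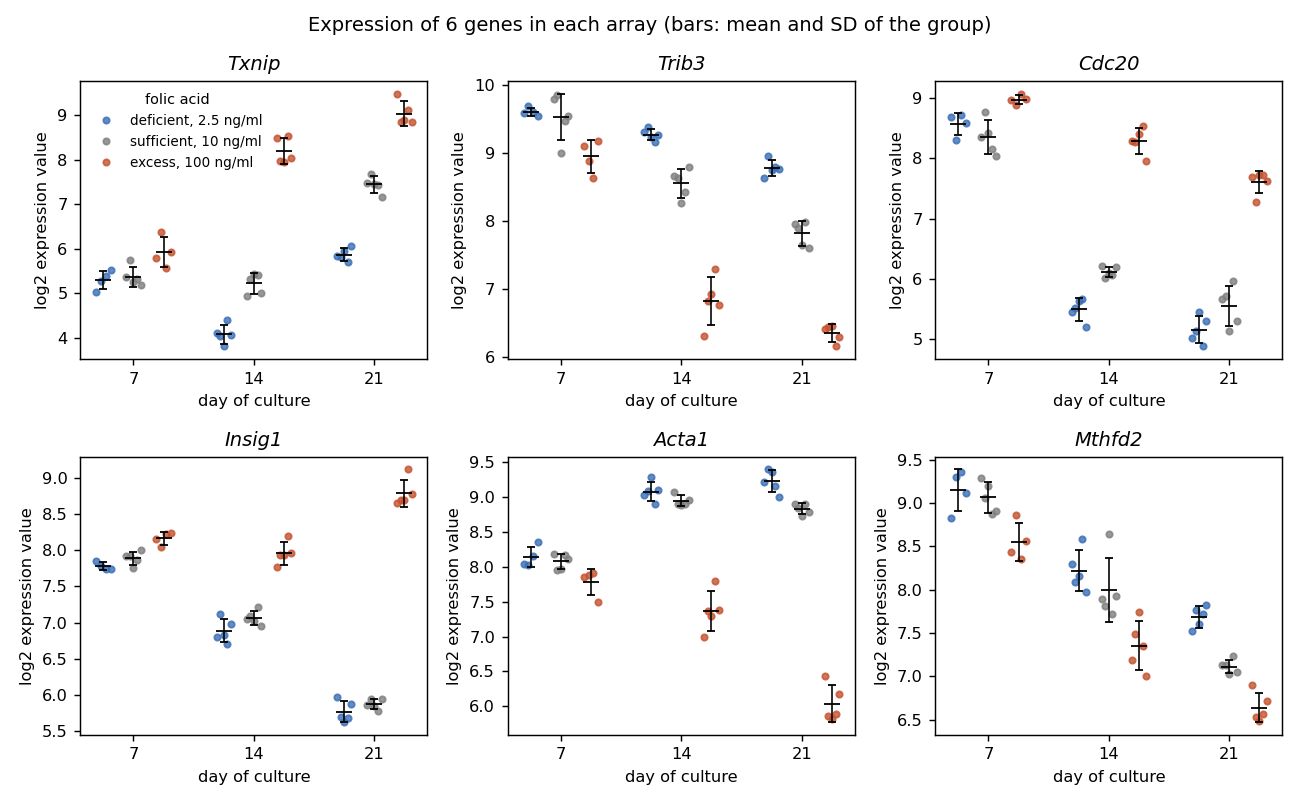
Log2 expression of 6 genes in each array (vertical axis) by day of culture (horizontal axis) and folic acid of the medium (colours); points are arrays and bars the mean and SD of the group. At day 21 Txnip lies at 5.87 in deficient, 7.45 in sufficient and 9.04 in excess medium, and Trib3 at 8.78, 7.82 and 6.35.

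**Figure D3:**
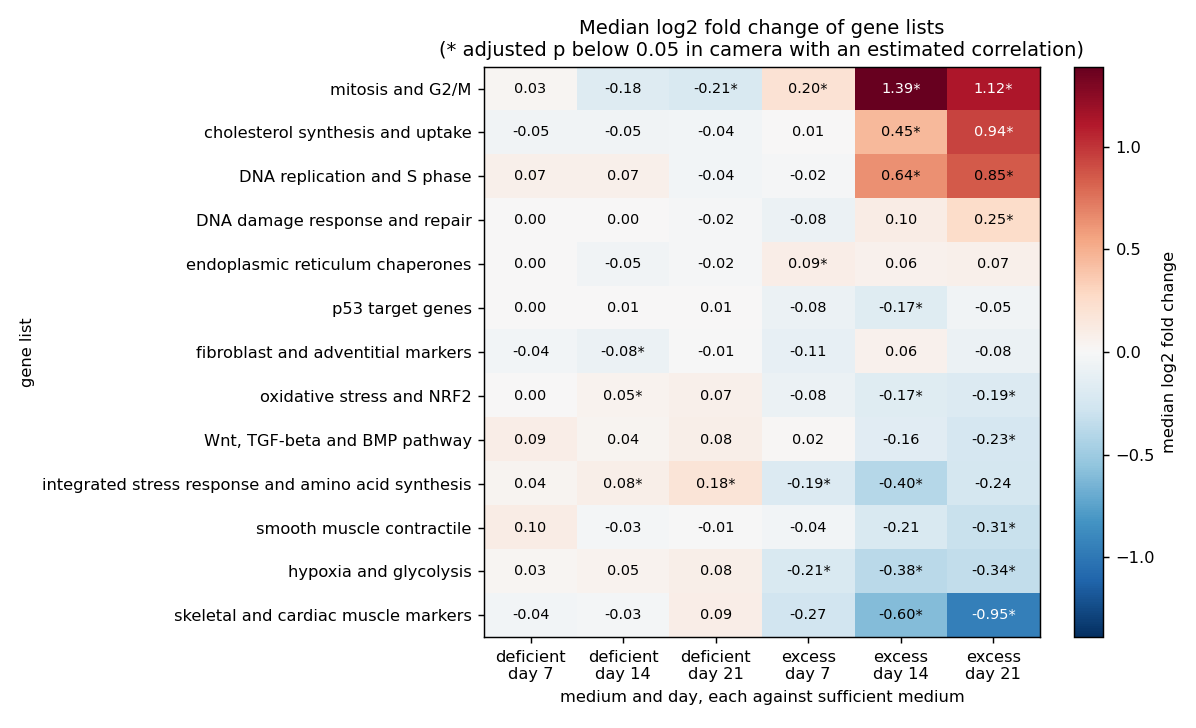
Median log2 fold change of 13 gene lists (rows) in deficient and in excess medium against sufficient medium at each day (columns), in numbers and colour; a star marks an adjusted p below 0.05 in camera with an estimated correlation. The mitosis list has -0.21 in deficient and 1.12 in excess medium at day 21.

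**Figure D4:**
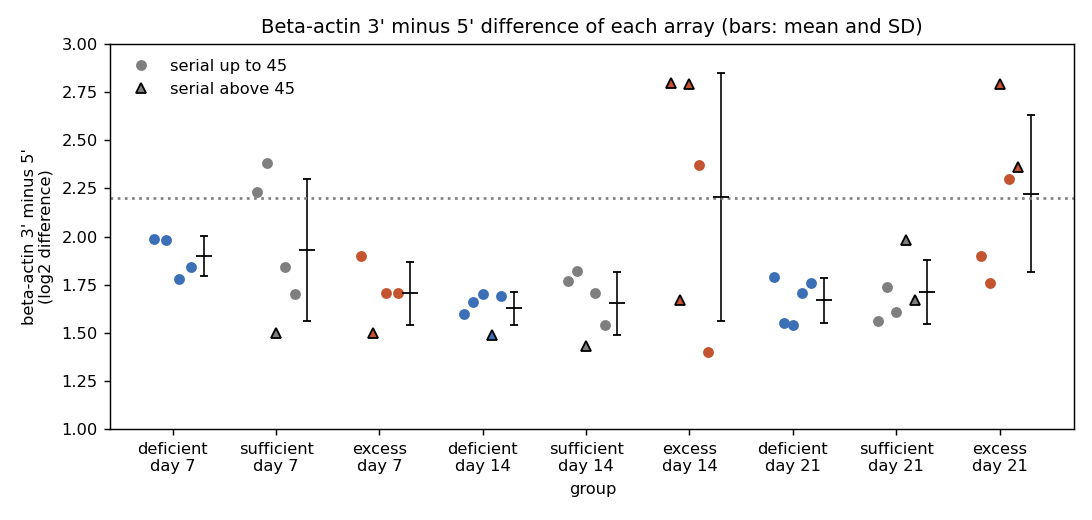
Difference between the 3' and 5' beta-actin control probe sets of each array (vertical axis, log2) by group (horizontal axis); circles are serials up to 45, triangles serials above 45, bars the mean and SD, and the dotted line the limit of 2.2. Above the limit lie 3 excess arrays at day 14, 3 at day 21 and 2 sufficient arrays at day 7.

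Genes that passed in excess medium were often shared between days. Of the 3743 genes at day 14 and 3974 at day 21, 1343 were higher at both days (496.7 for independent lists), 988 lower at both (329.4) and 60 opposite. At each of these days 3 of 5 excess arrays lay above the beta-actin limit, against 0 of 5 sufficient arrays. RNA integrity may thus have a share in this overlap and in the correlation of these effects, neither of which was computed without those arrays. Of the 216 genes at day 7, 20 were higher and 98 lower at both day 7 and day 14 (5.6 and 35.9 for independent lists), and 16 went in opposite directions. Across genes, which are not independent replicates, the excess effects at days 14 and 21 had r = 0.74 (exact permutation p = 0.0079, 0.1 after Benjamini-Hochberg adjustment over 13 such relations) and the deficiency effects at these days r = 0.38 ± 0.19 (jackknife SE; exact permutation p = 0.024, adjusted 0.16). The deficiency effect at day 7 had r = -0.24 with day 14 and r = -0.13 with day 21, at exact permutation p of 0.56 and 0.8. None of the 13 passed after adjustment. The p of 0.0079 for the excess effects is the smallest possible there, because exchanging the groups as a whole gives r of the same size. A single relation at that p cannot pass over 13 relations, so the adjusted value decides nothing about r = 0.74.

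The excess effect itself differed between days in tests added after these comparisons had been seen. Between day 21 and day 7 it differed for 2232 genes, 1547 higher and 685 lower, led by Lum, Insig1 and Idi1 at 2.83 ± 0.30, 2.64 ± 0.12 and 2.60 ± 0.14 and by Prnd, F3 and Tnnt1 at -3.91 ± 0.14, -2.73 ± 0.15 and -2.72 ± 0.21. Between day 21 and day 14 it differed for 783 genes, 358 higher and 425 lower, but 5 of 100 splits of the arrays, the real one included, called at least as many, and 293 passed without the arrays above the beta-actin limit. This difference was led by Insig1, Col25a1 and Slc29a1 at 2.02 ± 0.12, 1.91 ± 0.23 and 1.84 ± 0.15 and by Id2, Entrep1 and Id1 at -2.18 ± 0.22, -2.06 ± 0.19 and -1.92 ± 0.14. Lum at day 7 and in sufficient medium, Slc29a1 and Entrep1 at day 14, Col25a1 in sufficient medium at day 14 and Entrep1 in excess medium at day 21 were near background, so these differences are inexact. The cholesterol list was higher in both, with medians of 0.93 and 0.53 (adjusted p = 1.7e-05 and adjusted p = 5.1e-05 with an estimated correlation).

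Deficient and excess medium, compared directly, gave the widest range of folic acid. At day 7, 455 genes differed, 367 higher and 88 lower in deficient medium (n = 4 and 4), led by Mgp, Dsn1 and Cyp1a1, the last near background, at 1.00 ± 0.14, 0.89 ± 0.11 and 0.87 ± 0.12, and by Medag, near background, Hira, a histone chaperone, and Znrf3 at -0.82 ± 0.16, -0.74 ± 0.16 and -0.74 ± 0.13. The median difference of all genes was 0.06 there, so part of the balance toward higher genes may be a matter of scale. At day 14 there were 3666, 1534 higher and 2132 lower, led by Prnd, Trib3 and Cox6a2 at 2.65 ± 0.10, 2.44 ± 0.13 and 2.35 ± 0.10 and by Txnip, Kif20a and Cdc20 at -4.11 ± 0.14, -2.97 ± 0.17 and -2.79 ± 0.13. At day 21 there were 4628, 2034 higher and 2594 lower, led by Prnd, Myh2 and Id1 at 4.64 ± 0.10, 3.53 ± 0.17 and 3.29 ± 0.10 and by Txnip, Lum and Col25a1 at -3.17 ± 0.14, -3.06 ± 0.20 and -3.03 ± 0.16, where Myh2 in excess and Lum and Col25a1 in deficient medium were near background.

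In this direct comparison the integrated stress response list was higher in deficient medium at each day, with medians of 0.21, 0.50 and 0.43 (adjusted p = 0.036, 2.1e-05 and 0.0058 with an estimated correlation), and hypoxia and glycolysis genes likewise, with 0.27, 0.36 and 0.42 (0.036, 0.0038 and 0.0039). The mitosis list was lower at each day, with medians of -0.22, -1.58 and -1.34 (0.048, 4.1e-06 and 0.00019). At day 7 the count was 532 with the array series as a covariate and 760 in serials up to 45, and it went from 209 without deficient replicate 5 to 611 without excess replicate 6. At days 14 and 21 the counts with the covariate were 3522 and 4836, and in serials up to 45 they were 2567 and 4277. The beta-actin 3' minus 5' difference at day 14 was 2.21 ± 0.64 in excess and 1.63 ± 0.09 in deficient medium. At day 21 it was 2.22 ± 0.41 and 1.67 ± 0.12 (SD), so RNA integrity may have a share in these counts and their directions.

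Both effects at a day share the sufficient arrays, which by itself gives a positive correlation. At day 21 the deficiency and excess effects had r = -0.32 across genes, where simulated unchanged groups gave 0.5, and the covariance was -0.0191 against a simulated 0.00677. With the sufficient arrays split between the effects, the mean of 20 splits was r = -0.37. Of the 71 genes of deficient medium at day 21, 28 were higher there and lower in excess medium (7.1 for independent lists), 20 lower there and higher in excess medium (8.3) and 5 went the same way in both. At day 14 r was 0.09 (0.5 simulated, -0.07 over splits) with covariances of 0.00403 and 0.00674, and at day 7 it was 0.14 (0.44 simulated, -0.14 over splits) with 0.003 and 0.00677.

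Several lists were not called in any of the 6 comparisons against sufficient medium. Their medians in excess medium at day 21 were 0.22 for purine and pyrimidine synthesis (11 of 22 higher and 4 lower, the same adjusted over the list alone), -0.13 for the methionine cycle (2 of 13 higher and 3 lower) and -0.41 for imprinted genes (1 of 7 higher and 4 lower). They were 0.05 for senescence genes (5 of 16 higher and 3 lower) and -0.06 for inflammatory genes (3 of 13 higher and 4 lower), with the same numbers in each adjusted over the list alone. Lipid storage genes had a median of 0.00 and a mean of 0.06 while camera pointed down, and interferon genes had a median of -0.09 and a mean of 0.07. Matrix remodelling enzymes had a median of -0.21 (adjusted p = 0.058) and adipocyte markers -0.14 (adjusted p = 0.17). Extracellular matrix genes, called in deficient medium at the preset correlation only, and fibroblast markers, called there at day 14, were not called in excess medium. They had medians of -0.06 and -0.08 and means of 0.09 and 0.03 in excess medium at day 21.

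The folate list was not called in excess medium. At day 14, 8 of its 17 members fell and 2 rose, or 8 and 3 adjusted over the list alone (median -0.18, adjusted p = 0.0504), and at day 21, 5 fell and 6 rose, or 6 and 6 (median -0.10, adjusted p = 0.747). Mthfd1, a cytosolic enzyme of the folate cycle, and Mtrr, methionine synthase reductase, were higher at both days, by 0.37 and 0.50 at day 14 and by 0.37 and 0.52 at day 21. Aldh1l1, which removes formyl groups from folate, was lower at both, at -0.65 and -0.58, and Gcsh, of glycine cleavage, at -0.47 and -0.45. Median and test differed in sign in excess medium at day 14 for immediate early genes (median -0.06, mean 0.12, adjusted p = 0.773). In deficient medium at day 21 they differed for smooth muscle contractile genes (median -0.01, adjusted p = 0.97), lysosome genes (-0.01, 0.89), DNA repair (-0.02, 0.769), cholesterol synthesis (-0.04, 0.927) and matrix remodelling enzymes (-0.02, 0.927), where the test pointed up, none of them called.

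Markers of other cell types had 4 members each past the filter and were not tested as lists. In excess medium at day 21 the endothelial marker Ecscr was lower by -0.86 (adjusted p = 0.00019 in limma), and Flt1, Vwf and Egfl7 differed by 0.05, -0.16 and -0.29 with none past the threshold. The epithelial markers Krt8, Krt14, Krt7 and Dsp were lower, at -0.76, -0.37, -0.38 and -0.64. Of the macrophage and leukocyte markers Cd74 and Lcp1 were lower, at -0.86 and -0.45, Cd14 was higher at 0.64 and Cd3e differed by 0.00. In deficient medium at day 21 none of these passed, Cd74 coming closest at -0.52 (adjusted p = 0.051).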

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

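The rules that picked the values given first here were fixed before the data were examined. The tests of RNA integrity, of the array series, of serials 46 to 49 and of the sufficient arrays split between the effects were chosen after the results were seen. The correlation of deficiency and excess effects was chosen after the list results that point the same way had been seen, though before the correlation itself.

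The named genes, in the groups of their comparisons, and the beta-actin and Gapdh differences in each group were tested by the gap to the nearest array over the range. Single arrays stood apart from the others of their group in 22 of these 386 tests, where chance gives about 1 in 20, or 19.3. The tests share arrays and are not independent. Of the 22, 4 were in arrays with serials 46 to 49 and 4 in sufficient day 21 replicate 1. In sufficient day 21 replicate 1 these were Art3 at 8.23, S1pr1 at 11.29 and Ezh2 at 8.27 (log2), and a Gapdh 3' minus 5' difference of 0.41. In sufficient day 14 replicate 4, Mthfd2 was at 8.64 and Gadd45a at 10.94. Deficient day 7 replicate 1 had Mgp at 5.35 and Hira at 7.37. Mgp was at 4.80 in sufficient day 7 replicate 6, and the Gapdh difference was 0.13 in excess day 7 replicate 6. Others in excess medium were Idi1 at 8.24 (day 7 replicate 4), Tnnc2 at 10.43 (day 7 replicate 1), Uhrf1 at 7.96 (day 14 replicate 1) and Pfkp at 7.71 (day 14 replicate 5). At day 21 in excess medium they were Insig1 at 9.12 (replicate 4), Vegfa at 8.19 (replicate 5), Cdc20 at 7.27 (replicate 2) and Kif20a at 8.55 (replicate 1). The rest were Cdca3 at 5.79 (sufficient day 21 replicate 6), Vegfa at 9.35 (sufficient day 21 replicate 2), Folr1 at 4.47 (deficient day 21 replicate 6) and a Gapdh difference of 0.26 (deficient day 21 replicate 2).

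An interaction test found that the deficiency effect differed between day 21 and day 7 for Myh3 (1.22), Maoa (0.36), Txnip (-1.50) and Arhgap20l1 (-1.09), where Myh3 and Arhgap20l1 are inexact because their day 7 levels were near or under the filter limit. The calls of Maoa and Arhgap20l1 were lost in 7 of 32 and 13 of 33 settings. The excess effect differed for 2232 genes between day 21 and day 7 and for 783 between day 21 and day 14. Probe sets without a gene name, outside the genes tested, also carried signal. Of 3150 such probe sets, 20 passed in deficient medium at day 21, 1122 in excess medium at day 14 and 1104 in excess medium at day 21.

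Exchanging arrays between the groups of a comparison, over up to 100 splits with the real one included, showed how often a count as large arose. For deficient against sufficient medium it was 100 of 100 at day 7 (real count 0, highest other 16), 5 of 100 at day 14 (8, highest other 1250) and 1 of 100 at day 21 (71, highest other 3). Any split reaches a real count of 0, so the day 7 value was fixed in advance and tests nothing. For excess against sufficient medium it was 3 of 100 at day 7 (216, highest other 583), 1 of 100 at day 14 (3743, highest other 2609) and 1 of 100 at day 21 (3974, highest other 2098). For deficient against excess medium it was 1 of 35 at day 7 (455, highest other 393), 1 of 100 at day 14 (3666, highest other 2440) and 1 of 100 at day 21 (4628, highest other 2589). It was 1 of 100 for the deficiency effect between days (4, highest other 2) and for time in sufficient medium (5696, highest other 4190). For the excess effect it was 1 of 100 between day 21 and day 7 (2232, highest other 355) and 5 of 100 between day 21 and day 14 (783, highest other 1531). The split with 1250 genes at day 14 sets deficient replicates 1 and 5 and sufficient replicates 3, 4 and 5 against the rest, and serials 48 and 49 are among these. The Gapdh 3' minus 5' difference was 0.09 to 0.29 on that side and 0.29 to 0.41 on the other, so RNA integrity goes with this split as the serials do in part. It points to a structure of the samples other than folic acid, against which the number of genes at that day does not stand out, while Txnip kept its call in each setting.

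The genes that differ in excess medium at days 14 and 21 could reflect RNA integrity or the array series as well as folic acid. Without the 8 arrays above the beta-actin limit, the slope of the fold changes of the called genes on those of all arrays was 0.90 at day 14 and 0.94 at day 21. In serials up to 45 it was 0.97 at both days. These subsets share arrays with the full set, so the slopes count against either factor as the whole cause and leave a partial share open. The factors were tested separately, though the excess arrays with serials 53 to 56 all lie above the beta-actin limit. At day 14 only excess replicate 5 is free of both factors, so the slopes there cannot set aside the factors together. At day 21 the excess arrays under the limit, replicates 1 and 2, have serials 41 and 42. Folic acid remains an explanation, and these tests do not single it out.

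Genes moved in opposite directions in deficient and in excess medium at day 21, which a response graded with folic acid would give. Sharing the sufficient arrays works toward a positive correlation, so it could not give the pattern at that day. With these arrays split between the effects r lay between -0.41 and -0.28, an outcome that could hardly have pointed to sharing. The deficiency effect at day 21 and the excess effect at day 14, which share no array, had r = -0.22 (exact permutation p = 0.35), so it stays open whether the pattern extends between days. In serials up to 45 that correlation was -0.13 (exact permutation p = 0.5), so the array series is not settled between days. At day 21 itself, the lists called in both media kept opposite medians and their calls in serials up to 45. In deficient and excess medium these were -0.28 and 1.12 for mitosis and 0.18 and -0.28 for the stress response. They were 0.10 and -0.33 for hypoxia and 0.09 and -0.95 for skeletal muscle. These calls are at the preset correlation. With the array series as a covariate, skeletal muscle in deficient medium lost its call (adjusted p = 0.052 in camera). For mitosis, the stress response and hypoxia at day 21, the kept medians argue against the series above 45 as the cause. Serials up to 45 follow the order of the groups, so an effect of that order cannot be told apart from the media. The graded response stays open.

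Arrays with serials 46 to 49 stand apart from the other arrays of their groups. All 4 had the lowest first residual component of their group, but this is how they were noticed, so it does not test an array batch marked by the serials. RNA degradation in these arrays would raise the Gapdh 3' minus 5' difference, which was below the mean of the other arrays in 4 of 4 and counts against it. Deficient day 14 replicate 1, with a lower serial, came next in both the component (-12.8) and the Gapdh difference (0.15), so less intact RNA in the other arrays and a batch both stay open. No biological explanation was tested.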

How the results depend on the processing

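Normalization, filters, probe set choices, the replicate block, the series covariate, variance settings, array weights, the groups fitted and each array left out were chosen before the data were examined, and the settings on beta-actin and single serial ranges afterwards. The excess comparisons at days 14 and 21 and the change with time kept their counts within 1.5 times in the former settings. The small counts did not, and the cause was not tested. Named genes past the threshold kept their direction in each setting except Tgfb1 in excess medium at day 14, which was 0.29 in serials above 45. Sufficient medium has a single array there, so that value settles nothing. With every probe set tested, each gene was still read from the same probe set, so its direction could not change. Probe sets of the same gene did disagree in sign for 4 named genes. Array weights, trended variances, every probe set, the probe sets that may match several transcripts and the groups fitted were not varied for lists.

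Counts of genes that moved by over 1.5 times were as follows. Quantile normalization gave 140 for excess against sufficient medium at day 7. For deficient against sufficient medium at day 14, no filter gave 4, every probe set 5, and leaving out probe sets that may match several transcripts 3, with 1 for the deficiency effect between days. Trended and robust variances gave 7 for that effect. The series covariate gave 21 and 323 for deficient medium at days 14 and 21, 379 for excess at day 7 and 54 for the deficiency effect. Array weights gave 10, 106 and 300 for deficient medium at days 7, 14 and 21, 783 for excess and 1651 for deficient against excess at day 7, 59 for the deficiency effect, and 1532 for the excess effect between days 21 and 14. With only the groups compared, deficient medium had 1 and 43 at days 14 and 21, excess 0 at day 7, deficient against excess 198 at day 7, and the deficiency effect 2.

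The replicate block gave 3 for deficient medium at day 14, and 131 for excess against sufficient and 294 for deficient against excess medium at day 7. Over 133 pairs of arrays with the same number the mean correlation was -0.004, and 9 of 43 arrays correlated best with their own number. Over all groups together the numbers thus showed no pairing. Single pairs ran from -0.54 to 0.59, and pairing of the media within a day was not tested apart.

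The beta-actin covariate gave 5 and 107 for deficient medium at days 14 and 21. Without arrays above the beta-actin limit, deficient medium had 18 at day 14, excess 25, 2133 and 2619 at days 7, 14 and 21, deficient against excess 2201 at day 14, and the deficiency effect 13. The excess effect had 1222 between days 21 and 7 and 293 between days 21 and 14. In serials up to 45, deficient medium had 122 at day 21, excess 672 and 2294 at days 7 and 14, deficient against excess 760 at day 7, the deficiency effect 8 and the excess effect between days 21 and 14 had 392. In serials above 45, excess had 522 and 1934 at days 14 and 21, the former with 1 sufficient array and so without replication of that group. Without serials 46 to 49, day 7 had 637 for excess against sufficient and 726 for deficient against excess medium.

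With each array left out in turn, deficient medium had 0 (lowest, without deficient replicate 2 among others) to 1 (deficient replicate 1 or sufficient replicate 1) at day 7. At day 14 it had 1 (deficient replicate 1 or sufficient replicate 3) to 27 (sufficient replicate 5), and at day 21 32 (deficient replicate 3) to 73 (sufficient replicate 2). Excess medium at day 7 had 64 (excess replicate 3) to 544 (excess replicate 6), deficient against excess at day 7 209 (deficient replicate 5) to 611 (excess replicate 6), and the deficiency effect 2 (deficient day 7 replicate 5) to 7 (deficient day 7 replicate 1).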

Other observations

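The tests of Arrdc4 and of time given here were written after the results for Txnip and for the gene lists had been seen. Arrdc4, an arrestin-like relative of Txnip that shares with it a glucose-sensing transcriptional control, differed by -0.52 ± 0.13 in deficient medium at day 21 (adjusted p = 0.051 in limma, 95% interval -0.79 to -0.24), and Txnip by -1.58 (interval -1.87 to -1.28). A hypothesis is that glucose handling moves the pair together. By the rule written before the test, which asked Arrdc4 to pass the threshold, the prediction failed. Arrdc4 only just missed, and its whole interval has the sign of Txnip, so the failure does not count against a shared direction. The intervals do not overlap, so the changes differed in size. The hypothesis stays open.

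Of the genes that passed both in excess medium at day 14 and with time in sufficient medium, 1482 of 2475 went in opposite directions. Another 479 were higher in both (600.6 for independent lists) and 514 lower in both (565.9). A hypothesis is that cells in excess medium keep more of the earlier profile. With effects that share no array the correlation was -0.19 (exact permutation p = 0.28), and it was -0.15 without the mitosis and replication lists (exact permutation p = 0.32). The hypothesis stays open.

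Of the 49 genes past the threshold in both deficient medium at day 21 and excess medium at day 14, 46 had opposite signs. These comparisons share no array, but the genes are not independent, and the permutation over arrays that gave r = -0.22 across all genes had p = 0.35.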
